A study of Labrus bergylta with 24 samples.

How the data were processed

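RNA sequencing was performed on the hindgut (distal intestine) of 24 ballan wrasse, *Labrus bergylta*, a stomachless marine cleaner fish. There were 6 fish on each of 4 diets. Per the labels, the fish were acclimatized for 4 weeks on the reference diet and then fed for 5 weeks on the reference diet or on that diet with 0.7% soyasaponin, with 0.4% of a commercial prebiotic, or with both. Each diet was given to 2 tanks. The labels tie no fish to a tank, so tank and diet cannot be separated here, and the p-values treat the 6 fish of a diet as independent. Per the labels' protocols, stranded mRNA libraries were made from 90 ng of total RNA with a mean RNA integrity number of 7.8 ± 0.5 and were sequenced as paired ends, with an average library of 14.2 ± 1.4 M (mega) reads.

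The deposited table holds 20751 transcript features in 24 columns. Its unit is a signal: transcript counts divided by a size factor per library, deposited by the authors. Per the submitters' processing notes, cutadapt, TopHat2, featureCounts of the Subread package and DESeq2 were used, with no role, order or version attached. Tool versions, genome build and annotation are not given in the sources used here. The scale was read from the values. Dividing each column by its smallest value above 0 gave whole numbers in 100% of 498024 values, within 1e-06, so whole reads could be recovered. The deposited size factors, 0.803 to 1.42, equalled the median-of-ratios factors recomputed from those reads. The lowest total of a feature over the 24 libraries was 51 reads, so the table was already filtered on low totals or held no rarer feature. Recovered reads per library were 8.42 to 12.5 M, with a mean of 9.61 M. A listed value of 0 stands for 0 reads in that library. It allows an expected count of up to 3 reads at that depth, and this covers counting error only. Among 60 pairs of libraries from the same diet, the chi-square per degree of freedom of their reads was 21.1 to 102, so no pair differed by as little as sampling noise and every library counted as a separate fish.

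The features carry identifiers without gene names. None of them, 0 of 20751, matched the gene table of assembly fLabBer1.1 used here. The 29 gene lists (648 symbols) fixed before the data were examined could therefore not be tested, and neither could the cell type markers or a smooth muscle covariate. The rule for naming transcripts, also fixed beforehand, asked for genes with symbols. For features without one it allows the identifiers of at most 2 that rose and 2 that fell per comparison against control and per main effect. The largest log2 fold changes among those with adjusted p under 0.05 were taken, which gave 13 identifiers. Reads shared between near-identical copies were not examined.

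Values were taken as log2(normalized count + 1) for the 17056 features with a mean of at least 10 over all 24 libraries, leaving out 3695. The pseudocount understates the fold change of features with few counts. limma (version 3.58.1, R 4.3.3) was fitted with an intensity trend to the 4 diets at once, because the deposited values are normalized and not raw counts. Contrasts were each diet against control, the combined diet against each single addition, the interaction, and the main effect of each addition over both levels of the other (12 fish against 12). Tests were two-sided. A transcript was counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over all 17056, and unless another tool is named, every adjusted p is from limma. Library measures were compared with exact two-sided permutation tests over 924 arrangements, where the smallest possible p is 0.00216, adjusted over 24 comparisons. Distances between libraries were tested with vegan 2.7.1 and 99999 permutations. Plots were drawn with matplotlib 3.10.9.

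Alternatives fixed before the data were examined were the pseudocount (0.5 and 5), no filter and a mean of at least 50, recomputed size factors, quantile normalization, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on recovered reads, robust moderation, array quality weights, only the diets compared in the fit, an adjusted p under 0.1, and leaving out each fish in turn. Added after seeing the data were the first principal component or log2 size factor as covariate, leaving out the 2 libraries least like the others, a random block described in the closing section, thinning to equal reads, and removal of co-varying transcripts. DESeq2 gave no adjusted p for 344 transcripts in the comparison of soyasaponin with control, and these stayed out of its counts. Replicate numbers follow the order of the records and pair no fish.

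The tests were checked on a single draw of simulated counts per comparison, with 200 changed transcripts. Transcripts were drawn independently with the same dispersion on all diets. Variation shared between transcripts and unequal spread of the diets were therefore not simulated. For soyasaponin against control, over 16892 transcripts, limma recovered 25.4% of 1.5-fold, 62.7% of 2-fold and 84.8% of 4-fold changes, and 5.74% of its calls were false. edgeR gave 5.04% false calls and DESeq2 18.7%. For the soyasaponin main effect, over 16886 transcripts, limma recovered 35.8%, 68.7% and 84.8% at the same fold sizes with 4.55% false calls, edgeR gave 4.44% false calls and DESeq2 15.9%.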

Results

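The hindgut transcriptome of ballan wrasse was measured in 24 fish, 6 on each of 4 diets: a reference diet (control), the reference diet with 0.4% prebiotic, with 0.7% soyasaponin, or with both (the combined diet). Soyasaponins are triterpenoid glycosides of soybean, and prebiotics are feed additives meant to act through gut microbes. The question put by the feeding design was how each addition, alone and together, alters the intestine. Recovered reads per library had a median of 9.44 M (mega, range 8.42 to 12.5 M) in control, 9.04 M (8.63 to 10.6 M) in prebiotic, 10.4 M (9.38 to 11.2 M) in soyasaponin and 9.01 M (8.55 to 9.50 M) in combined fish (n = 6 each). The most abundant transcript took 5.44 ± 1.03% of normalized counts in prebiotic fish and 3.35 ± 1.48% in control fish (SD, n = 6 each). That difference had an exact permutation p of 0.0173 and an adjusted p of 0.312 over 24 comparisons. The fish of a diet shared 2 tanks, so differences between diets include differences between tanks. Transcripts are given by identifier, since no gene names were paired with them.

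Most variation between libraries did not follow diet. The first principal component held 31.5% of the variance and the second 9.76%. Soyasaponin accounted for 6.89% of the squared distances between libraries (permutation p = 0.0781), the prebiotic for 5.29% (permutation p = 0.184) and their interaction for 4.75% (permutation p = 0.251). Diets differed in spread (permutation p = 0.0333): the mean distance of a fish to the centre of its diet was 98.4 ± 14.5 in prebiotic fish and 78.9 ± 7.98 in control, 78.2 ± 16.8 in soyasaponin and 80.5 ± 9.94 in combined fish (SD, n = 6 each, log2 units). Prebiotic replicates 4 and 5 correlated least with the other libraries, with median correlations of 0.853 and 0.839.

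**Figure D1:**
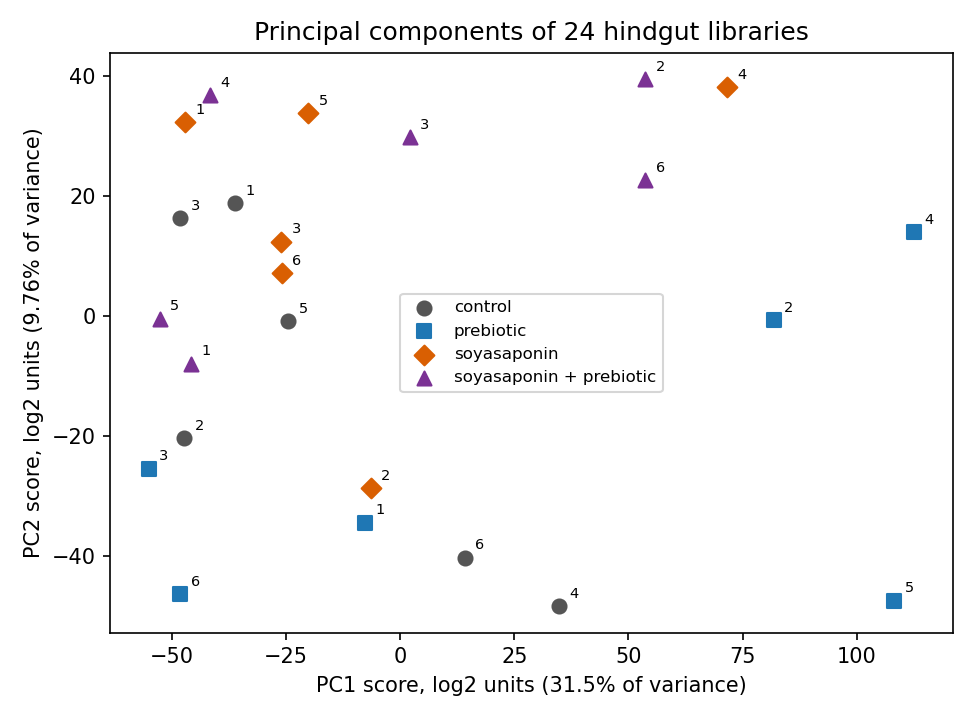
Scores of the 24 libraries on the first (x axis, 31.5% of variance) and second (y axis, 9.76%) principal components of log2(normalized count + 1), with the replicate number beside each point. Prebiotic replicates 4 and 5 lie farthest right, and the diets overlap on both axes.

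A set of 340 transcripts followed the first component with a correlation above 0.9. Their summed share of normalized counts ran from 0.0898% to 6.03% between fish, a 67.2-fold range, and exceeded 1% in 6 libraries. It was 0.353 ± 0.355% in control, 2.49 ± 2.77% in prebiotic, 0.554 ± 0.950% in soyasaponin and 0.650 ± 0.781% in combined fish (SD, n = 6 each). The median share was 0.168% in control, 1.65% in prebiotic, 0.149% in soyasaponin and 0.194% in combined fish. No difference from control in the mean share was detected, which does not exclude one: prebiotic against control gave an exact permutation p of 0.160 and an adjusted p of 0.578. With limma, 0 of the 340 were changed in any of the 8 contrasts. They had been chosen for following the first component, on which the diets overlap, so this count is no separate evidence.

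**Figure D2:**
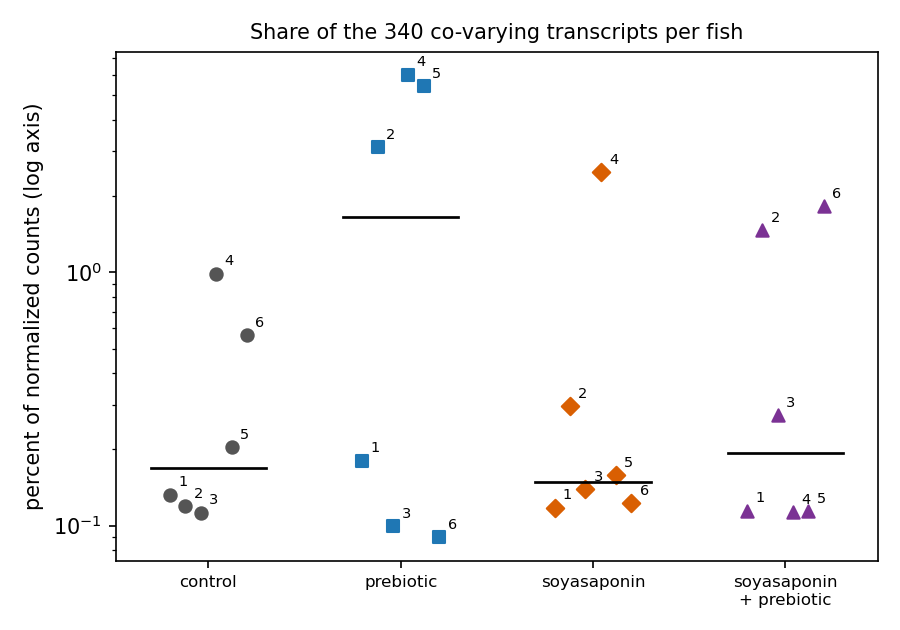
Share of normalized counts taken by the 340 co-varying transcripts in each fish (y axis, percent, log axis) by diet, with replicate numbers and a bar at the median of each diet. The highest fish of each diet stood at 0.988% in control, 6.03% in prebiotic, 2.49% in soyasaponin and 1.83% in combined fish.

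The soyasaponin main effect had the highest count of changed transcripts of the 8 contrasts in limma. Over both prebiotic levels, 1017 of 17056 transcripts (5.96%) differed between the 12 fish given soyasaponin and the 12 fish not given it, with 693 higher and 324 lower. Most changes were small: the median absolute log2 fold change was 0.50, while 55 transcripts rose and 31 fell by at least 2-fold. The largest rise was in LABE_00058622-RA, with 21.9 ± 13.7 normalized counts in control and 18.8 ± 16.0 in prebiotic fish against 232 ± 198 in soyasaponin and 173 ± 129 in combined fish (SD, n = 6 each). Its log2 fold change was 3.24 (SE 0.45, adjusted p = 0.00131). LABE_00037047-RA rose from 168 ± 197 and 189 ± 208 in control and prebiotic fish to 552 ± 260 and 527 ± 403 in soyasaponin and combined fish (SD, n = 6 each), by 2.26 on the log2 scale (SE 0.58, adjusted p = 0.0234). The largest fall was in LABE_00010136-RA, at -2.52 (SE 0.43, adjusted p = 0.00240), from 7.43 ± 4.88 and 37.5 ± 28.5 to 1.39 ± 1.18 and 2.64 ± 2.16 normalized counts in the same order of diets (SD, n = 6 each). LABE_00046348-RA was far more abundant and fell from 4587 ± 4683 and 3783 ± 1083 to 1029 ± 1321 and 990.2 ± 778.7 (SD, n = 6 each), a log2 fold change of -2.39 (SE 0.59, adjusted p = 0.0178). Each of the 4 moved past the median of the fish without soyasaponin in 12 of 12 fish given it. LABE_00010136-RA passed the filter on mean counts only through the prebiotic fish. Soyasaponin and combined fish held 0 to 5 reads of it, against 2 to 15 in control and 8 to 88 in prebiotic fish. Its fall thus ended near 0 reads. The estimated fall was larger with prebiotic than without, but this interaction was not detected (-1.64, adjusted p = 0.426). With edgeR, LABE_00037047-RA had an adjusted p of 0.0762. Of the 1017 transcripts, 551 had an abundance in the top tercile, above a mean of 272 normalized counts, and 424 of those were higher, while in the bottom tercile, below 67.6, 148 were changed, 64 higher and 84 lower. In 1003 of the 1017 the difference had the same sign with and without prebiotic, which selection on the mean effect favours. edgeR called 1085 transcripts. The count was 1538 without soyasaponin replicate 2, 646 without combined replicate 2 and 1181 without prebiotic replicates 4 and 5, and DESeq2 gave 1604. The excess of higher transcripts varied, with 768 higher and 211 lower under quantile normalization, 953 and 651 in DESeq2, 756 and 580 with the first principal component as covariate, and 667 and 514 without prebiotic replicates 4 and 5.

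**Figure D3:**
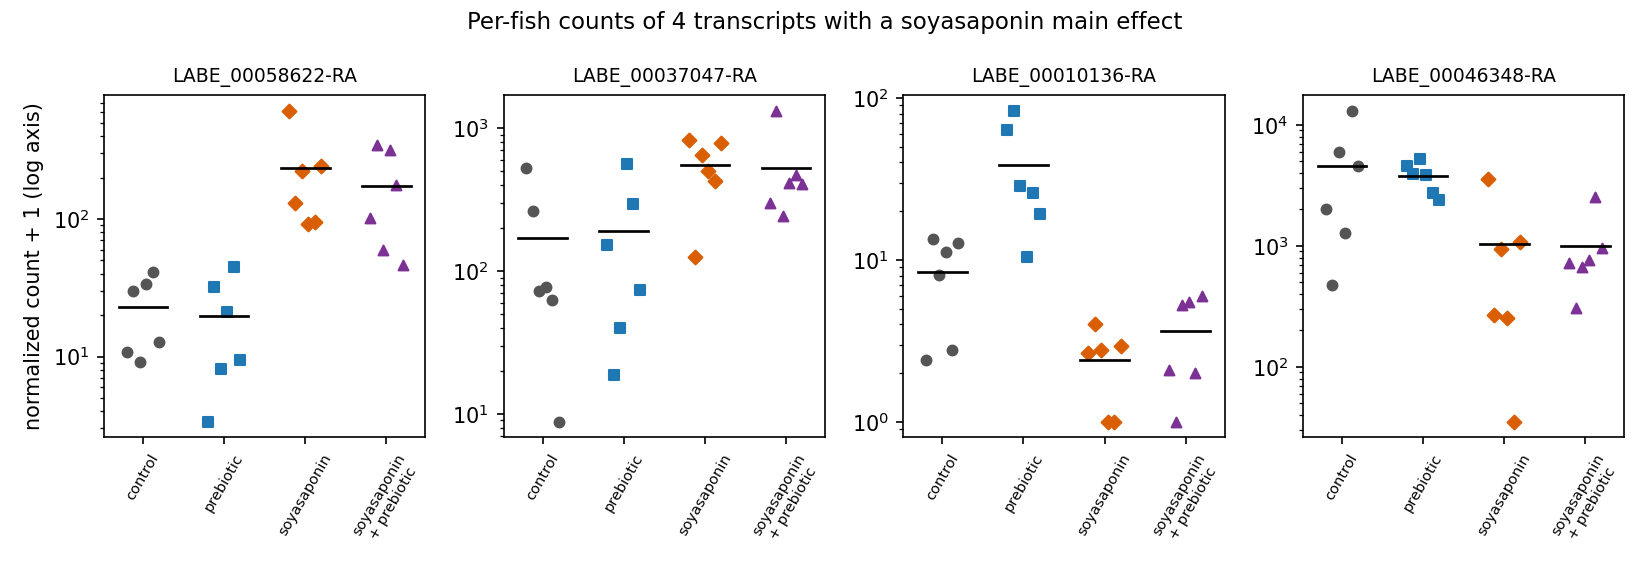
Normalized counts plus 1 (y axis, log axis) of the 4 transcripts named for the soyasaponin main effect, by diet, with a point per fish and a bar at the mean of each diet (n = 6). LABE_00058622-RA and LABE_00037047-RA were higher on both diets with soyasaponin, and LABE_00010136-RA and LABE_00046348-RA were lower.

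**Figure D4:**
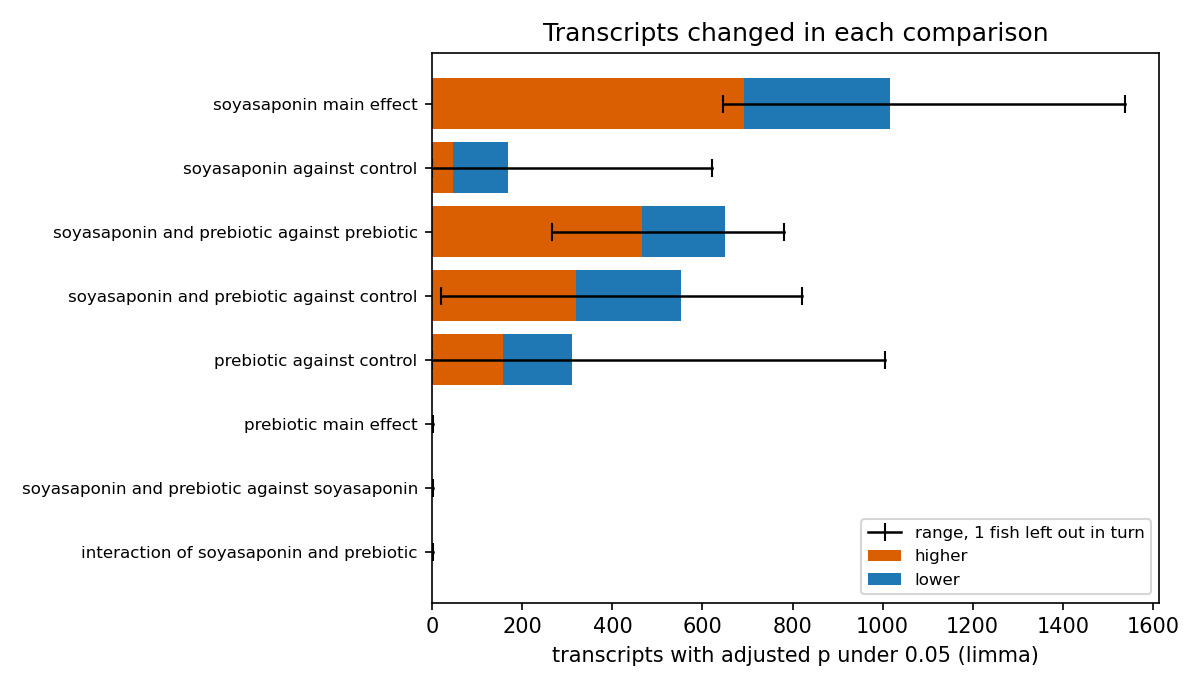
Number of transcripts with an adjusted p under 0.05 in limma (x axis) in each comparison, split into higher and lower, with black lines from the lowest to the highest count when each fish was left out in turn. The soyasaponin main effect stayed between 646 and 1538, while soyasaponin against control ran from 0 to 621 and prebiotic against control from 0 to 1006.

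Against the reference diet, soyasaponin alone changed 168 transcripts, and more of them fell than rose, 121 against 47. The fallen ones had a median log2 fold change of -1.01 and the risen ones 0.55, and 61 fell and 8 rose by at least 2-fold. LABE_00082737-RA rose from 0.928 ± 1.10 normalized counts in control to 28.05 ± 21.66 in soyasaponin fish (SD, n = 6 each), with a log2 fold change of 3.41 (SE 0.66, adjusted p = 0.0212). It stood at 7.04 ± 4.48 in prebiotic and 7.21 ± 3.79 in combined fish, so it passed the filter at a mean of 10 only through the soyasaponin fish. LABE_00058622-RA rose by 3.25 (SE 0.63, adjusted p = 0.0212). LABE_00037806-RA fell from 101 ± 62.7 to 14.0 ± 3.95 (SD, n = 6 each), at -2.53 (SE 0.50, adjusted p = 0.0234), and LABE_00035077-RA fell from 4475 ± 2051 to 1443 ± 2155 (SD, n = 6 each), at -2.52 (SE 0.59, adjusted p = 0.0426). All 6 soyasaponin fish lay beyond the control median for the former 3 transcripts and 5 of 6 for LABE_00035077-RA, whose adjusted p in edgeR was 0.196. For LABE_00082737-RA this includes soyasaponin replicates 2 and 5, with 2 and 3 reads where control fish had 0 to 3. The groups did not overlap in 216 of the 17056 transcripts, where chance gives 36.9.

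This count rested on individual fish. It was 0 in limma without control replicate 3 (2372 at an unadjusted p under 0.05, edgeR and DESeq2 not run on that subset), 4 without soyasaponin replicate 6, 7 without soyasaponin replicate 5, 43, 76 and 82 without control replicates 2, 1 and 4, 46, 106 and 621 without soyasaponin replicates 4, 1 and 2, 80 without combined replicate 3, 90 without prebiotic replicate 1, and 276 without prebiotic replicates 4 and 5. At an unadjusted p under 0.05 all 24 fish gave 2730 transcripts where chance gives 853, edgeR called 193 and DESeq2 609, and a fit of these 2 diets alone called 15. The excess of falls shrank to 22 higher and 24 lower without soyasaponin replicate 4, 86 and 106 without control replicate 5, and 439 and 615 with array quality weights. The calls of LABE_00082737-RA were lost without control replicate 3 or soyasaponin replicate 6, those of LABE_00058622-RA and LABE_00037806-RA without either of these or soyasaponin replicate 5, with adjusted p up to 0.0711. That of LABE_00035077-RA was lost without any 1 of the 6 controls, of soyasaponin replicates 4, 5 and 6, of prebiotic replicates 1 and 2, or combined replicate 3, with adjusted p up to 0.108. Over all omissions the log2 fold changes ran from 3.10 to 3.93 for LABE_00082737-RA and 2.90 to 3.47 for LABE_00058622-RA. They ran from -2.78 to -2.33 for LABE_00037806-RA and -3.12 to -2.08 for LABE_00035077-RA.

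The combined diet changed 553 transcripts against control, 319 higher and 234 lower, with 81 rising and 64 falling by at least 2-fold. LABE_00064073-RA rose from 24.2 ± 13.2 to 227 ± 186 normalized counts (SD, n = 6 each), a log2 fold change of 3.11 (SE 0.59, adjusted p = 0.0159), with 92.4 ± 73.9 in soyasaponin fish. LABE_00058622-RA rose by 2.77 (SE 0.63, adjusted p = 0.0232). LABE_00004558-RA fell from 139 ± 142 to 8.40 ± 13.1 (SD, n = 6 each), at -4.20 (SE 0.95, adjusted p = 0.0231), and LABE_00035077-RA fell from 4475 ± 2051 to 589 ± 427 (SD, n = 6 each), at -3.08 (SE 0.59, adjusted p = 0.0159). LABE_00004558-RA was also low in prebiotic (13.9 ± 14.3) and soyasaponin fish (22.8 ± 38.5), so its control mean stood apart from every other diet. That mean rested largely on control replicates 3 and 5 (350 and 290). The other controls held 32.2 to 66.1, against 38.8 in prebiotic replicate 6, 34.4 in combined replicate 5 and 100 in soyasaponin replicate 1. All 6 combined fish lay beyond the control median for each of the 4. edgeR called 489 transcripts (279 higher, 210 lower), while lower transcripts slightly outnumbered higher ones in DESeq2, 618 higher and 629 lower, and in a fit of these 2 diets alone, 327 higher and 344 lower. The count was 19 without combined replicate 2, 247 and 253 without combined replicates 4 and 3, 264, 199, 207, 322 and 361 without control replicates 1, 2, 3, 4 and 6, and 795 without prebiotic replicates 4 and 5. It was 332 under quantile normalization, 1708 with array quality weights and 218 with the log2 size factor as covariate, where LABE_00058622-RA and LABE_00004558-RA had adjusted p of 0.0568 and 0.0647. Without combined replicate 2 each of the 4 named calls was lost, those of LABE_00058622-RA and LABE_00004558-RA were also lost without control replicate 3, and that of LABE_00058622-RA without combined replicate 4, with adjusted p up to 0.0714 over these omissions.

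Between the fish given prebiotic, soyasaponin on top of the prebiotic gave 649 transcripts with an adjusted p under 0.05, of which 465 were higher and 184 lower. Of 100 splits of these 12 fish, the real one included, 5 gave at least as many, so chance assignment of fish is not excluded for this count. Of the 1017 transcripts with a soyasaponin main effect, 455 were among these, 99 were among the 168 of soyasaponin against control, and 10 were in both. edgeR called 776, with 633 higher and 143 lower, DESeq2 called 1239, with 731 higher and 508 lower, and quantile normalization gave 641 higher and 98 lower. The count was 420, 386 and 424 without prebiotic replicates 2, 4 and 5, 266 and 348 without combined replicates 2 and 3, and 298 without prebiotic replicates 4 and 5 together, of which 160 were higher and 138 lower.

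The prebiotic alone changed 310 transcripts against control, 157 higher and 153 lower, with 16 rising and 40 falling by at least 2-fold. LABE_00072855-RA rose from 16.5 ± 8.86 to 78.9 ± 37.5 normalized counts (SD, n = 6 each), a log2 fold change of 2.21 (SE 0.43, adjusted p = 0.0241), and LABE_00003377-RA from 23.7 ± 9.05 to 102 ± 66.4 (SD, n = 6 each), at 1.97 (SE 0.40, adjusted p = 0.0241). LABE_00016633-RA fell from 26.6 ± 14.9 to 3.53 ± 3.90 (SD, n = 6 each), at -2.95 (SE 0.75, adjusted p = 0.0457), and LABE_00023345-RA from 111 ± 47.4 to 28.5 ± 18.4 (SD, n = 6 each), at -2.11 (SE 0.48, adjusted p = 0.0316). LABE_00023345-RA was also low in soyasaponin (33.6 ± 20.1) and combined fish (36.5 ± 21.9), so its control mean stood apart from every other diet. All 6 prebiotic fish lay beyond the control median for each of the 4. LABE_00016633-RA had an adjusted p of 0.0689 in edgeR, 0.0643 under quantile normalization and 0.0638 with a pseudocount of 5. With the first principal component as covariate 13 transcripts were called and the 4 named had adjusted p of 0.0616 to 0.104. With the log2 size factor as covariate 0 were called in limma (1939 at an unadjusted p under 0.05, edgeR and DESeq2 not run with it) and the 4 had adjusted p of 0.131 to 0.357, the sign of each unchanged by either covariate. In the order named, their log2 fold changes were 2.41, 2.58, -2.61 and -1.94 with the size factor covariate. They were 2.18, 1.79, -2.83 and -1.74 with the first principal component. The balance of higher and lower transcripts depended on scaling and tool, with 65 higher and 205 lower under quantile normalization and 103 higher and 199 lower in edgeR, and DESeq2 called 1579 with 989 higher and 590 lower.

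The prebiotic count also rested on individual fish, with 0 in limma without prebiotic replicate 5 (2762 at an unadjusted p under 0.05, edgeR and DESeq2 not run on that subset), 44 and 172 without prebiotic replicates 4 and 2, 1006 without prebiotic replicate 6, 71, 49, 67 and 22 without control replicates 1, 2, 3 and 5, 645 without control replicate 4, and 11 without prebiotic replicates 4 and 5 together. At an unadjusted p under 0.05, all 24 fish gave 3685 transcripts in limma, edgeR called 302, and a fit of these 2 diets alone called 4 (0 higher, 4 lower). The calls of the 4 named transcripts were all lost without prebiotic replicate 5 or control replicate 5. Those of LABE_00003377-RA, LABE_00016633-RA and LABE_00023345-RA were also lost without prebiotic replicate 4 or control replicate 2, and those of the last 2 without prebiotic replicate 2 or control replicates 1 and 3. LABE_00016633-RA lost its call without prebiotic replicate 3, soyasaponin replicates 5 and 6 or combined replicates 3, 4, 5 and 6 as well, and adjusted p reached 0.112. Over all omissions the log2 fold changes ran from 1.98 to 2.43 for LABE_00072855-RA and 1.69 to 2.11 for LABE_00003377-RA. They ran from -3.27 to -2.62 for LABE_00016633-RA and -2.34 to -1.75 for LABE_00023345-RA.

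No effect of the prebiotic over both soyasaponin levels was detected by limma or edgeR. The prebiotic main effect changed 0 transcripts in limma (smallest adjusted p = 0.123, 2528 at an unadjusted p under 0.05), 0 in edgeR and 131 in DESeq2. Adding prebiotic to soyasaponin changed 0 in limma (smallest adjusted p = 0.276, 933 at an unadjusted p under 0.05, where chance gives 853), 0 in edgeR and 7 in DESeq2. The interaction of the additions changed 0 in limma (smallest adjusted p = 0.128, 2174 at an unadjusted p under 0.05), 0 in edgeR and 94 in DESeq2. The limma count became 1 for the prebiotic main effect without control replicate 4, control replicate 5 or soyasaponin replicate 4, for prebiotic on top of soyasaponin without combined replicate 6, and for the interaction without prebiotic replicate 2. So limma and edgeR did not show, for any transcript, that the difference between prebiotic and control fish was unlike that between combined and soyasaponin fish.

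Soyasaponin alone and the combined diet shared 78 changed transcripts, 38 higher and 40 lower on both, with 0 in opposite directions. Independent lists of those sizes would share 0.879 higher and 1.66 lower. The other pairs of diets set against these controls also shared changed transcripts, with 40 for soyasaponin and prebiotic (16 higher, 24 lower) and 54 for prebiotic and the combined diet (22 higher, 32 lower), again 0 in opposite directions. Independent lists would share 0.433 higher and 1.09 lower in the former pair and 2.94 higher and 2.10 lower in the latter. Every one of these pairs uses the same control fish, so independent lists are not what unchanged diets would give. The control fish also carry the highest sample numbers, and anything tied to that order would enter each pair. Across transcripts, which are not independent replicates, the log2 fold changes of soyasaponin alone and of the combined diet against control correlated at 0.716. Both of these comparisons use the same control fish. Unchanged diets simulated against shared controls gave a mean correlation of 0.498 (0.0434 to 0.840 over 100 draws). The covariance was 0.151 against a simulated 0.0924 ± 0.0634 (SD), a difference of 0.0590 that is within that spread. With the controls split 3 and 3 in each of 20 ways, the correlation averaged 0.281 (0.120 to 0.397), and 0 to 3 calls were shared between lists of 0 to 54 and 0 to 289. Under the same splits, soyasaponin and prebiotic shared 0 to 1 calls with a mean correlation of 0.135 (-0.187 to 0.371), and prebiotic and the combined diet 0 to 7 with 0.165 (-0.158 to 0.404). For prebiotic and soyasaponin against control the correlation was 0.449 where the simulation gave 0.498, and for prebiotic and the combined diet 0.474 where it gave 0.475. The simulated draws shared 0 calls in each of these pairs. Unchanged diets have only false calls to share, so this can reflect few calls and does not weigh the overlap by itself.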

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

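Among the tests in this part, those of library depth, diet, size factor and overlap with the co-varying transcripts were chosen after the result was seen, and thinning to equal reads and both covariates were settings added after seeing the data. The share of normalized counts taken by the 340 co-varying transcripts was 2.49% in soyasaponin replicate 4, against 0.118% to 0.295% in the other 5 fish of that diet. A sample stood apart by a gap above 0.625 of its group's range in 11 of 72 groups of 6 fish tested. Chance gives 3.6 for normally distributed values. All 11 samples stood high, in counts or shares not taken as logs, which can be skewed, so 3.6 is not a fair count for them. The named transcripts had also been picked for large changes and are not independent, so the number of 11 is not itself a test. Soyasaponin replicate 1 held 4 of these, all high: 614 normalized counts of LABE_00058622-RA (others 91.3 to 242), 5797 of LABE_00035077-RA (others 153 to 1038), 100.4 of LABE_00004558-RA (others 0.977 to 15.4) and 3588 of LABE_00046348-RA (others 34.2 to 1080.1). Combined replicate 2 had 103 normalized counts of LABE_00016633-RA (others 3.30 to 18.8) and 1332 of LABE_00037047-RA (others 243 to 471). Combined replicate 5 had 34.4 of LABE_00004558-RA (others 0.990 to 9.55) and 2517 of LABE_00046348-RA (others 303 to 968). LABE_00003377-RA stood at 234 in prebiotic replicate 2 (others 62.4 to 104) and at 114 in soyasaponin replicate 4 (others 20.2 to 53.0).

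The 340 co-varying transcripts, chosen because they follow the first principal component, had a 67.2-fold range of their share between fish, which depth does not account for: the share and recovered reads had a Spearman rho of 0.0217 (permutation p = 0.920) over 24 fish, with a Pearson r of -0.0886 (permutation p = 0.685) for the log10 share, and -0.156 without the 2 fish farthest from the median depth. Diet stays open, since the variance of the log10 share between diets had a permutation p of 0.498, which does not exclude a difference. Admixed material, such as a neighbouring tissue taken with the sample, may be a source and predicts fixed ratios between these transcripts. In the 6 fish with a share above 1% the median SD of the log2 ratio to their total was 0.238, under the 0.5 set beforehand, but 100 random sets of other transcripts gave 0.370 (lowest 0.320), so that bound was too loose to decide, a comparison added after the value was seen. The slopes of single transcripts on the mean of the set also ran from 0.408 (10th percentile) to 1.66 (90th percentile), which unequal expression in the gut itself could give too, so without gene names admixture and a state of the gut wall cannot be told apart here.

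The 310 calls of prebiotic against control were the second pattern weighed, because limma gave 0 with a log2 size factor covariate (1939 at an unadjusted p under 0.05, where edgeR and DESeq2 were not run with it) and 13 with the first principal component as covariate. Unequal numbers of reads do not explain them, as 239 calls were made after thinning every library to the same total, 231 of them shared. A trend with size factor as the whole cause would lower the fold. The median absolute log2 fold change of the called transcripts was 0.67 before and 0.57 with that covariate (0.59 with the first principal component, median SE 0.15). The median SE rose from 0.15 to 0.18 with the size factor covariate, and why the calls ended was not tested. These transcripts had been selected for this difference, and diet itself accounted for 44.0% of the variance of the log2 size factor. The fold therefore does not decide about such a trend. The co-varying transcripts made up 0% of the calls, which their choice by the first principal component made likely. Calls outside them could still rest on the same fish, with 11 left without prebiotic replicates 4 and 5. So an effect of the prebiotic, a trend with size factor and these individual fish remain open.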

How the results depend on the processing

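The soyasaponin main effect was past the threshold under every alternative run, with 646 to 1786 transcripts, and the single-diet comparisons were less stable. Leaving out each fish in turn gave 0 to 621 transcripts for soyasaponin, 0 to 1006 for prebiotic and 19 to 820 for the combined diet against control, 266 to 781 for the combined diet against prebiotic, 646 to 1538 for the soyasaponin main effect, and 0 to 1 for prebiotic on top of soyasaponin, for the interaction and for the prebiotic main effect. In what follows S, P and C stand for soyasaponin, prebiotic and combined diet against control, and M for the soyasaponin main effect, with 168, 310, 553 and 1017 transcripts as reported.

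DESeq2 called 609 (S), 1579 (P), 1247 (C), 1604 (M), 1239 for the combined diet against prebiotic, 94 for the interaction, 131 for the prebiotic main effect and 7 for prebiotic on top of soyasaponin. Its share of false calls was also higher in the simulation. An adjusted p under 0.1 gave 576 (S), 1149 (P), 1470 (C), 1786 (M) and 1209 for the combined diet against prebiotic. Array quality weights gave 1054 (S), 170 (P), 1708 (C), 1726 (M) and 1 for the prebiotic main effect. Fitting only the diets compared gave 15 (S) and 4 (P), but 671 (C) and 492 for the combined diet against prebiotic. Quantile normalization gave 79 (S) and 332 (C). Among alternatives added after seeing the data, the first principal component as covariate gave 320 (S), 13 (P) and 1 for the prebiotic main effect. The size factor covariate gave 0 (P, limma, 1939 at an unadjusted p under 0.05), 218 (C) and 338 for the combined diet against prebiotic. Leaving out prebiotic replicates 4 and 5 gave 276 (S), 11 (P), 298 for the combined diet against prebiotic and 1 for the prebiotic main effect. A random block of sample number runs gave 388 (S), 653 (P) and 992 (C), with an estimated correlation within runs of -0.0405, so these added calls are no evidence of a shared unit or for the calls. Splitting the controls moved the correlation of S with C from 0.716 to a mean of 0.281. The split comparisons share no control fish and each uses only 3, and the parts of these were not told apart. The causes of the changed counts were not tested. Pseudocounts, filters, recomputed size factors, robust moderation, edgeR, thinning and removal of the co-varying transcripts kept every count within 1.5 times.

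For named transcripts, 81 of 96 values under 6 alternatives kept direction and call, 15 lost the call and 0 reversed. These were a pseudocount of 5, quantile normalization, edgeR, robust moderation and the size factor and first principal component covariates. DESeq2, array quality weights and fits of only the diets compared were not among them. The fit of prebiotic and control alone called 0 higher transcripts, so LABE_00072855-RA and LABE_00003377-RA lost their calls there. Gene list tests and the smooth muscle covariate were not run, for lack of gene names. No paired analysis was possible because the replicate numbers only follow the order of the records. In the simulation 25.4% of 1.5-fold changes were recovered for S. It drew transcripts independently with the same dispersion on all diets, so recovery in these fish may differ. How depth limits the counts was not tested, since thinning only removed the inequality of reads between libraries.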

Other observations

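Some transcripts were close to absent in some fish and abundant in others. With at most 1 read in at least 3 fish and at least 100 normalized counts in at least 3 fish, 178 transcripts were of this kind, and 112 of them clustered together, 111 being among the 340 co-varying transcripts, for which a difference between diets stays open. A separate cluster of 17 transcripts averaged 127 to 4299 normalized counts in 11 fish and 0.416 to 16.2 in the other 13: 3 control, 4 prebiotic, 2 soyasaponin and 2 combined fish were high (Fisher's exact p = 0.808). A cluster of 6 transcripts averaged 82.4 to 1103 in 9 fish and 1.04 to 17.5 in the rest, with 4 control, 1 prebiotic, 2 soyasaponin and 2 combined fish high (Fisher's exact p = 0.463). These p-values do not exclude a difference between diets. None of the transcripts in these 2 clusters was changed against control in limma (0 calls).

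Other splits of the fish into groups of the same sizes were drawn, 100 per comparison with the real one. For the soyasaponin main effect 1 of 100, the real split, gave as many as 1017 transcripts, and the highest other gave 1. The combined diet against control also had 1 of 100 (real 553, highest other 347). As 1 of 100 is the smallest share these splits can give, they argue against chance assignment of fish in both without excluding it. For soyasaponin against control (2 of 100, real 168, highest other 254) and prebiotic against control (2 of 100, real 310, highest other 438) the share was below 0.05, but another split gave more transcripts than the diets did. These splits treat fish as exchangeable and so say nothing about tanks or about the weight of individual fish. Chance stays open for the combined diet against prebiotic, where 5 of 100 splits gave at least 649 and the highest other gave 1472. Why that split gave so many was not tested. For the 3 comparisons with 0 transcripts any split gives as many (100 of 100), so the count of splits decides nothing there; the highest other was 2 for prebiotic on top of soyasaponin, 4 for the interaction and 11 for the prebiotic main effect.

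The numbers in the sample names fall into 8 runs of up to 6 consecutive numbers, 2 per diet with 3 fish each, and what a run stands for is not stated. Every control fish carries a higher number than any fish of the other diets. Anything tied to that order cannot be told apart from the control diet, and a test within diets cannot see it. A hypothesis raised after seeing the names was that a run is a tank or another shared unit that could inflate the soyasaponin calls. Fish of a run would then deviate together. Residual correlations within a diet averaged -0.173 within runs and -0.214 between runs, a difference of 0.0410 with an exact permutation p of 0.2437 over 10000 arrangements. This neither shows nor excludes such units, and tank and diet cannot be told apart here because the labels tie no fish to a tank.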
